A study of Homo sapiens with 12 samples.

How the data were processed

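The series measured HCT116, a human colorectal cancer cell line, with 3 assays. RNA-seq compared cells carrying a control hairpin (shCtrl, 2 libraries) with cells carrying a hairpin against YTHDF1 (shYTHDF1, 2 libraries), both delivered by lentivirus per the labels' protocols. RIP-seq sequenced the RNA that came down with FLAG-tagged YTHDF1 (IP, 1 library) and the matching input (1 library), from cells transfected with a plasmid that overexpresses the tagged protein. MeRIP-seq, in which fragments are pulled down with an antibody against N6-methyladenosine (m6A), was done on shCtrl cells (1 IP and 1 input) and on 2 shYTHDF1 samples (1 IP and 1 input each). Per the labels' protocols, the RNA-seq libraries were made with a stranded kit that selects mRNA, and the RIP and MeRIP libraries with a stranded total RNA kit for low input. RNA-seq and RIP values were therefore compared across kits only where this is said.

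The authors deposited 1 table of read counts per gene for the 4 RNA-seq and 2 RIP libraries, made with HTSeq 0.6.1, with hg38 as the genome, per the submitters' processing notes. The aligner, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes may be split differently from how the transcripts were made. The summary rows of the table were left out of library sizes and tests. They held reads outside genes, 2.89% to 3.78% of the uniquely aligned reads of the RNA-seq libraries, and reads in overlapping genes, 5.03% to 5.41%. Reads that aligned at more than 1 place made up 44.2% to 47.8% of the reads of the RNA-seq libraries, 62.1% of the RIP IP and 97.6% of the RIP input. Genes with near-identical copies, among them ribosomal protein genes with many pseudogenes, are undercounted by this step. The authors deposited 3 m6A peak lists, 1 per IP library, each line with the exon blocks of a peak, its gene and 1 p-value. The peak caller, its threshold and whether the p-value was adjusted are not given in the sources used here. Column values name 1 IP library per list, so the peaks were called per library, and no signal per peak was used here. All peaks of a gene carried 1 shared p-value in 50.9% (shCtrl), 49.8% (shYTHDF1-1) and 57.4% (shYTHDF1-2) of the genes with several peaks, so the authors' p-value was used only to rank within a list.

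RNA-seq counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood test, 2-sided, no covariate), with Benjamini-Hochberg adjusted p under 0.05 as the threshold over 15111 genes. Standard errors of log2 fold changes were derived from the fitted coefficient and its F statistic. CPM values use TMM-scaled library sizes for RNA-seq and total gene counts for RIP. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM, adjusted over the 20 lists with at least 5 tested members, with an estimated correlation and fry, which tests against no change, beside it. The labels do not say whether libraries of a group came from separate cultures or from separate hairpins. The p-values therefore measure the spread between these libraries, which may be technical. The replicates of a group were checked for duplication: the chi-square per degree of freedom of their counts was 5.27 for shCtrl and 59.3 for shYTHDF1, so no pair agreed within sampling noise.

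For RIP, with 1 IP and 1 input, no test was run. Genes with at least 100 counts in the 2 libraries together were compared by the ratio of CPM with a pseudocount of 1, and a ratio of at least 2-fold was called enriched or depleted. Intervals of a ratio are exact 95% intervals from the binomial share of the IP counts, without the pseudocount. They cover counting error only, since reads without molecular identifiers are not independent molecules. A list's median ratio was set against 10000 random lists matched on input CPM. Peaks were compared by overlap of exon blocks of at least 1 bp on the same strand. The share of a gene list with a shCtrl peak was set against 10000 expression-matched draws among protein-coding genes at 1 CPM or more in each RNA-seq library. Gene biotype and gene span (chromosome, start and end) came from NCBI RefSeq on GRCh38.p14, the same assembly as hg38; 35335 of 56269 gene rows matched, and 12824 of the 14014 with at least 100 counts. Exon annotation and genome sequence were not used here, so positions within UTRs, motifs and GC content are not reported.

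Before the data were examined, the tests, the alternatives, the 21 gene lists and the rule for genes named in the text were fixed. The rule takes YTHDF1 and ARHGEF2, which the series is titled after, always. For RNA-seq it takes up to 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with both shYTHDF1 libraries outside the range of the shCtrl libraries and a mean of at least 1 CPM, plus up to 4 members per list with the smallest p. For RIP it takes the 10 highest and the 10 lowest ratios of protein-coding genes and up to 4 most extreme members per list. For m6A it takes all peaks on YTHDF1 and ARHGEF2, up to 10 genes with the best ranked peaks in all 3 lists, and up to 5 genes each with peaks only in shCtrl or only in both shYTHDF1 lists. Alternatives covered other size factors, count filters, DESeq2 1.42.0, limma-voom, a fold threshold, the replicate number as a block, leaving out each library, other RIP totals, minimums and pseudocounts, and other peak overlaps and ranks. Results of 1 list and of some genes taken by the rule are not reported here.

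The steps were tested on simulated data. In counts drawn for 14887 genes from the RNA-seq means, dispersions and library sizes, edgeR recovered 11.9% of 67 genes changed 1.5-fold, 58.2% of 67 changed 2-fold and 100% of 66 changed 4-fold, and called 9 unchanged genes. Both simulated groups had the same dispersion per gene. The real groups differed in spread (SD of 0.14 log2 units for shCtrl and 0.34 for shYTHDF1), so these rates may not carry over. Of 100 random lists with no shift, camera gave 2 an unadjusted p under 0.05. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.72 (ribosomal proteins). This rate therefore does not show how often camera calls correlated lists without a shift. The matched random lists placed 8 of 100 unshifted lists outside the middle 95% and a list shifted by 1 log2 unit at percentile 100. Figures were drawn with matplotlib 3.10.9, and Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.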

Results

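HCT116 cells were profiled by RNA-seq, by sequencing of RNA bound to FLAG-tagged YTHDF1 (RIP-seq) and by m6A MeRIP-seq, 12 libraries in all. YTHDF1 is a cytoplasmic protein that binds m6A in mRNA, and the design asks which transcripts it targets in colorectal cancer cells. Gene counts summed to 28165727 and 28420703 in shCtrl 1 and 2, and to 28791961 and 28293288 in shYTHDF1 1 and 2. The RIP IP held 31455141 gene counts and the RIP input 5982750, so input counts set the precision of the RIP ratios. The m6A lists held 11918 peaks (shCtrl), 12153 (shYTHDF1-1) and 10989 (shYTHDF1-2). The depth of the MeRIP libraries is not given in the sources used here.

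The RNA-seq comparison asked which transcripts changed level with the YTHDF1 hairpin. YTHDF1 itself (chromosome 20, 63195429 to 63216131, hg38) was at 69.9 and 72.8 CPM in the shCtrl libraries and at 24.3 and 36.5 CPM in the shYTHDF1 libraries, 2.35-fold lower (log2 fold change -1.23, SE 0.20, edgeR quasi-likelihood adjusted p = 0.0303). That call was lost without shCtrl 1 (adjusted p = 0.235), without shCtrl 2 (0.292) and with no filter on low counts (0.0832), at log2 fold changes of -1.21 to -1.27, and held in the other alternatives (adjusted p = 3.5e-06 to 0.0317). ARHGEF2, a guanine nucleotide exchange factor (chromosome 1, 155946854 to 155979617), was at 107.7 and 112.5 CPM in shCtrl and 141.8 and 120.5 CPM in shYTHDF1. Its log2 fold change was 0.25 (SE 0.13, edgeR adjusted p = 0.227), so no change of its mRNA passed the test. Over the alternatives its log2 fold change ranged from 0.12 to 0.38, and it passed only without shYTHDF1 2 (adjusted p = 0.00594).

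Of 15111 genes tested, 785 were higher and 760 lower in shYTHDF1, and 269 and 183 of these by at least 2-fold. Among the genes that fell most, FN1, which encodes fibronectin, fell from 17.2 ± 0.538 to 2.10 ± 0.837 CPM (SD, n = 2 in each group here and below), and TGM2, a protein cross-linking transglutaminase, from 31.9 ± 0.603 to 4.61 ± 0.0103 CPM, 6.91-fold. The adhesion molecule MCAM fell 5.28-fold, from 72.6 ± 0.983 to 13.8 ± 2.72 CPM, the endothelial lipase LIPG 9.67-fold and the prostaglandin transporter SLCO2A1 13.8-fold, the last from only 2.01 ± 0.323 CPM. The chemokine receptor CXCR4 (6.68-fold), the homeobox gene SIX2 (6.5-fold), the interleukin receptor subunit IL1RAP (6.18-fold), ILDR2 (5.35-fold) and the collagen prolyl hydroxylase P3H2 (4.75-fold) completed the 10 largest decreases. Without shYTHDF1 1 the log2 fold change of IL1RAP was -3.30 in place of -2.63, and without shYTHDF1 2 that of CXCR4 was -3.62 in place of -2.74. The adjusted p values of these 10 genes ranged from 0.0136 (TGM2) to 0.0303 (CXCR4).

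Among the genes that rose most, the calcium-binding protein S100A4 went from 35.2 ± 0.212 to 135 ± 25.1 CPM (3.83-fold) and ADIRF from 46.0 ± 2.00 to 182 ± 25.6 CPM (3.96-fold). ZNF385A, a zinc finger protein, was at 61.4 and 58.3 CPM in shCtrl and at 184 and 310.02 CPM in shYTHDF1 1 and 2. CLIC3 (6.32-fold), the hyaluronidase HYAL1 (6.01-fold), FXYD3 (5.08-fold) and the lipocalin LCN2 (4.93-fold) rose from under 2 CPM; without shYTHDF1 1 the log2 fold change of HYAL1 was 1.90 in place of 2.59. ZSCAN31 (4.12-fold), the mitochondrial sulfide oxidoreductase gene SQRDL (3.80-fold) and the ferritin pseudogene FTLP3 (3.92-fold) also rose. The log2 fold change of ZSCAN31 was 1.24 without shYTHDF1 2, in place of 2.04, and that of FTLP3 1.30 without shYTHDF1 1, in place of 1.97. FTLP3 counts are uncertain, since its reads resemble those of the parent gene. Adjusted p values in this group ranged from 0.0176 (ADIRF) to 0.0457 (ZSCAN31).

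How many genes passed depended on single libraries. Without shCtrl 1 edgeR called 0 genes higher and 4 lower (TGM2, MCAM, FN1 and AK4), and without shCtrl 2 it called 0 and 3 (TGM2, MCAM and AK4), while 1990 and 1633 genes had an unadjusted p under 0.05. AK4, an adenylate kinase named here after its values were seen, was 4.72-fold lower with all libraries. Without shYTHDF1 1 it called 2853 higher and 3322 lower, and without shYTHDF1 2 it called 3673 and 3796; each such fit assumes that the lone library varies like the other group. Of 23 genes picked for naming that did not pass with all libraries, 13 passed without shYTHDF1 1 and 17 without shYTHDF1 2. The shYTHDF1 libraries differed more from each other (SD of 0.34 log2 units over genes at 1 CPM or more) than the shCtrl libraries did (0.14). With no filter on low counts 0 genes passed in edgeR, although 5163 had an unadjusted p under 0.05. DESeq2 called 1079 higher and 1132 lower and limma-voom 732 and 775.

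Of 41 tested S phase and DNA replication genes, 12 fell and none rose past the threshold over all genes, and 20 fell and 1 rose when adjusted over the list alone. CDC6, which loads the replicative helicase, fell from 161 ± 4.48 to 80.7 ± 10.6 CPM, the clamp loader subunit RFC5 from 83.8 ± 1.65 to 50.4 ± 1.94 and the polymerase epsilon subunit POLE2 from 55.6 ± 2.95 to 34.5 ± 0.782. The list median was 1.27-fold lower (camera adjusted p = 3.95e-07, but 0.694 with an estimated correlation and 0.0516 by fry). Of 40 G2 and mitosis genes, 14 fell and none rose, or 21 and none when adjusted over the list alone, with a median 1.32-fold lower (camera adjusted p = 3.95e-07, but 0.726 with an estimated correlation and 0.0825 by fry). Here the spindle checkpoint kinase BUB1B went from 65.0 ± 2.30 to 30.6 ± 0.597 CPM and its relative BUB1 from 146 ± 5.65 to 90.2 ± 1.62.

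Of 24 tested cholesterol synthesis genes, 8 fell and 2 rose (17 and 2 when adjusted over the list alone), with a median 1.64-fold lower and a camera adjusted p of 7.67e-05 (0.726 with an estimated correlation and 0.253 by fry). MSMO1 went from 74.6 ± 3.72 to 25.1 ± 9.25 CPM, IDI1 from 115 ± 7.54 to 46.1 ± 8.55 CPM and the sterol carrier STARD4 from 17.3 ± 0.0799 to 6.81 ± 0.620 CPM. TM7SF2, a sterol reductase of the same pathway, rose from 20.4 ± 0.249 to 72.0 ± 2.51 CPM. PMVK, a mevalonate pathway kinase named after its values were seen, rose 1.86-fold. Of 33 glycolysis and hypoxia genes, 9 fell and 2 rose (17 and 4 when adjusted over the list alone; camera adjusted p = 0.00513, but 0.694 with an estimated correlation and 0.0516 by fry). Its members BNIP3 and BNIP3L, mitophagy receptors induced by hypoxia, fell 2.04-fold and 1.59-fold, and PFKFB4, a regulator of glycolytic flux, fell 1.90-fold. The members that rose, named after their values were seen, were the glycolytic enzymes PKM (1.63-fold) and PFKL (1.46-fold).

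Cytosolic ribosomal protein genes were higher in 72 of 74 members, with a median 1.31-fold higher (camera adjusted p = 3.95e-07, but 0.726 with an estimated correlation and 0.360 by fry). Random lists matched on expression and gene span had a median of 0.24 log2 units, against 0.39 for these genes. Span was matched in broad groups only, so part or all of the rise may go with the span trend described below. Only 4 of the 74 genes passed on their own, among them RPLP2, RPLP1 and RPS19, which rose 1.67-fold to 1.84-fold, and 0 passed when adjusted over the list alone. Their share of the gene counts was 4.72% and 4.58% in the shCtrl libraries, 6.96% in shYTHDF1 1 and 5.37% in shYTHDF1 2. Of 29 p53 target genes, 6 rose and none fell (9 and none when adjusted over the list alone), among them BBC3, a proapoptotic BH3 gene, from 28.9 ± 0.131 to 62.4 ± 3.28 CPM, and FDXR, from 151 and 144 CPM in shCtrl to 275 and 401 CPM in shYTHDF1 1 and 2; PLK3 and SESN2 rose 1.69-fold and 1.77-fold. BAX (1.76-fold) and GDF15 (2.63-fold) also rose and were named after their values were seen. The camera adjusted p of that list was 0.0453 (0.726 with an estimated correlation and 0.485 by fry), but its median change was -0.13 log2 units in shYTHDF1 1 and 0.55 in shYTHDF1 2. The call was lost with no filter on low counts (adjusted p = 0.102), without shCtrl 1 (0.0598) and without shCtrl 2 (0.0633), and without shYTHDF1 2 the direction turned (0.663).

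**Figure D1:**
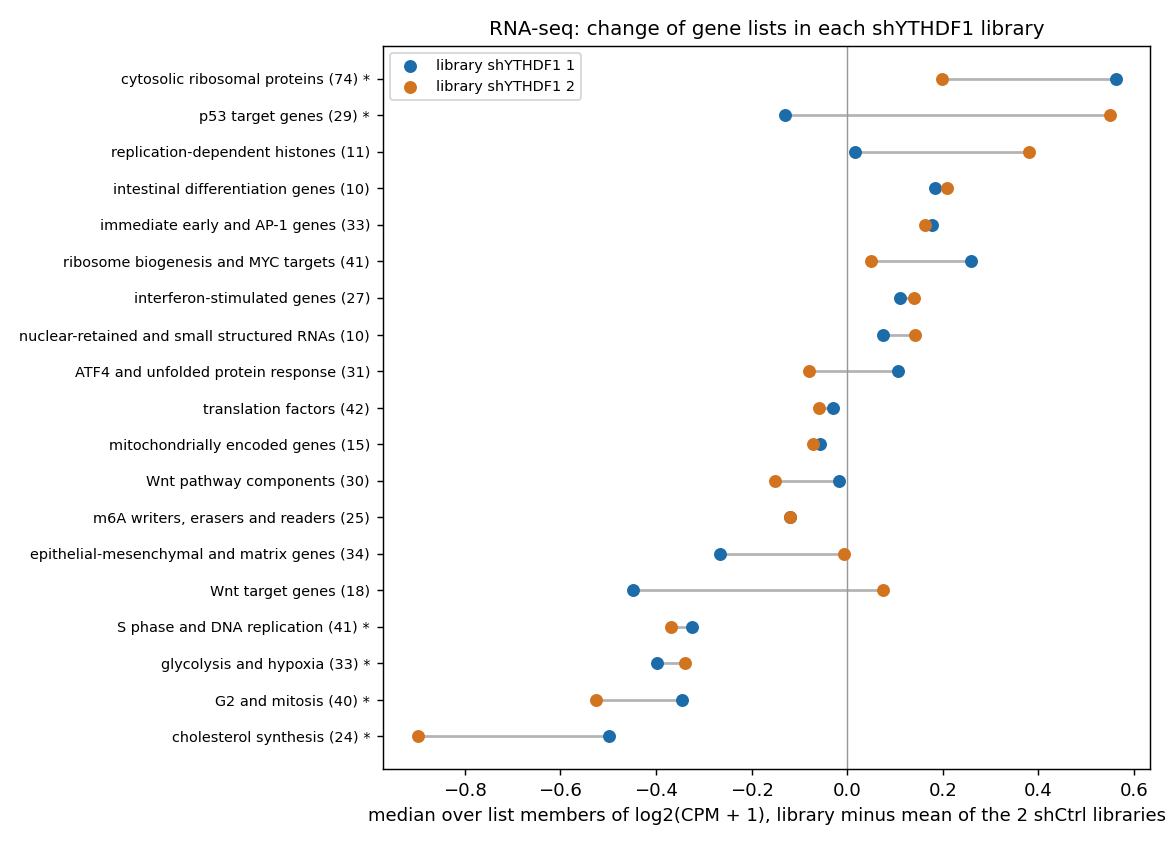
Each row is a reported gene list fixed in advance, with its number of tested members in parentheses and a star where camera with the preset correlation called it. Points give the median over members of log2(CPM + 1) in 1 shYTHDF1 library minus the mean of the 2 shCtrl libraries, joined by a line. Cholesterol synthesis lay lowest in both libraries (-0.50 and -0.90). The p53 targets (-0.13 and 0.55), Wnt target genes (-0.45 and 0.07) and ATF4 and unfolded protein response genes (0.11 and -0.08) differed in sign between the libraries.

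The other 13 lists with enough members were not called by camera, with adjusted p values of 0.183 to 0.962. Of 25 m6A writers, erasers and readers, 3 fell and 1 rose (4 and 1 when adjusted over the list alone): IGF2BP2, an m6A reader, from 302 ± 4.06 to 177 ± 15.04 CPM, the translational regulator FMR1 from 34.4 ± 1.22 to 21.3 ± 1.29 CPM and the methyltransferase adaptor RBM15 from 35.5 ± 2.63 to 23.0 ± 0.428 CPM, while its paralog RBM15B rose from 41.4 ± 0.0455 to 91.6 ± 6.33 CPM. Of 18 Wnt target genes only EPHB2 passed (1.68-fold lower), and 0 passed when adjusted over the list alone. DKK1 (log2 fold change -0.50, adjusted p = 0.118), NOTUM (-0.53, 0.142) and SOX9 (-0.81, 0.168) did not pass; SOX9 was at 134 CPM in shYTHDF1 1 and 302 CPM in shYTHDF1 2, against 378 and 387 CPM in shCtrl. Without shYTHDF1 2, camera called the Wnt target list (adjusted p = 0.000719), ribosome biogenesis and the epithelial-mesenchymal list (each 0.0287). Of 30 Wnt pathway components, WNT11 fell 2.90-fold and PORCN rose 1.59-fold, while WNT6 (adjusted p = 0.0668) and DVL1 (0.0746) did not pass, and 1 member passed when adjusted over the list alone. Interferon-stimulated genes gave 4 higher of 27 (IFI35 2.63-fold, ISG15 2.59-fold, BST2 3.06-fold and IFI6 2.06-fold), and 4 higher and 2 lower when adjusted over the list alone.

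Of 34 epithelial-mesenchymal and matrix genes, 3 rose and 3 fell (3 and 4 when adjusted over the list alone), the urokinase PLAU (1.55-fold), its receptor PLAUR (1.54-fold) and S100A4 higher, and FN1 lower with TWIST1 (2.30-fold) and ITGA6 (1.88-fold), both named after their values were seen. In the ATF4 and unfolded protein response list, 2 of 31 rose (CEBPB 1.77-fold, SDF2L1 1.498-fold) and 2 fell (HYOU1 1.97-fold, PDIA6 1.59-fold), with 4 and 2 when adjusted over the list alone. Immediate early and AP-1 genes gave JUNB (1.73-fold) and JUND (2.27-fold) higher and KLF6 (1.64-fold) lower of 33, with SPRED2 at an adjusted p of 0.0539, and 4 higher and 3 lower over the list alone. Among 42 translation factors, EIF5B (1.67-fold) and EEF1D (1.64-fold) rose and EIF2S1 (1.44-fold), EIF1AX (1.43-fold) and EIF4H (1.48-fold, named after its values were seen) fell, the same counts over the list alone. Ribosome biogenesis and MYC targets had ODC1 1.40-fold higher and DDX21 1.41-fold lower of 41, with SRM (adjusted p = 0.0506) and GRWD1 (0.0605) beyond the threshold and 0 passing over the list alone. FCGBP (2.88-fold) and KRT19 (1.55-fold) rose of 10 intestinal differentiation genes, also over the list alone, and CA2 (adjusted p = 0.189) and KRT20 (0.233) did not pass. Of 15 mitochondrially encoded genes MT-ND2 (1.57-fold) and MT-ND6 (1.80-fold) rose, the same 2 counts over the list alone, and MT-CO1 (adjusted p = 0.1004) and MT-ND1 (0.103) did not pass. The mean log2 fold change of that list was 0.07, while camera ranked it slightly lower. None passed of 11 replication-dependent histones (lowest adjusted p, 0.0809 for HIST1H1C), of 10 nuclear-retained and small structured RNAs (lowest, 0.0526 for NEAT1) or of the 2 tested markers of fibroblasts, endothelium and leukocytes (COL1A1, adjusted p = 0.599, and VWF, 0.348). The nuclear-retained RNAs had a median log2 fold change of 0.14 and a mean of -0.13. Genes with histone names took only 0.00339% and 0.00267% of the gene counts in shCtrl 1 and 2. Their share was 0.241% in the RIP input, made with the total RNA kit, so the RNA-seq held few histone reads. Without shCtrl 1, camera called the histones (adjusted p = 0.0255) and the nuclear-retained RNAs (0.0094).

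The change also followed gene span, a pattern examined after it was seen. Among 11579 protein-coding genes at 1 CPM or more, the 10% with the shortest span (median 3.71 kb) had a median log2 fold change of 0.33, with 16.6% called higher and 1.30% lower. In the 10% with the longest span (median 243 kb) the median was -0.20, with 1.12% called higher and 8.98% lower. The Spearman correlation of change with span across genes, which are not independent replicates, was -0.36 in shYTHDF1 1 and -0.27 in shYTHDF1 2. Libraries of the same group differed along span too, with a correlation of -0.15 for shCtrl 1 minus 2 and -0.17 for shYTHDF1 1 minus 2.

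**Figure D2:**
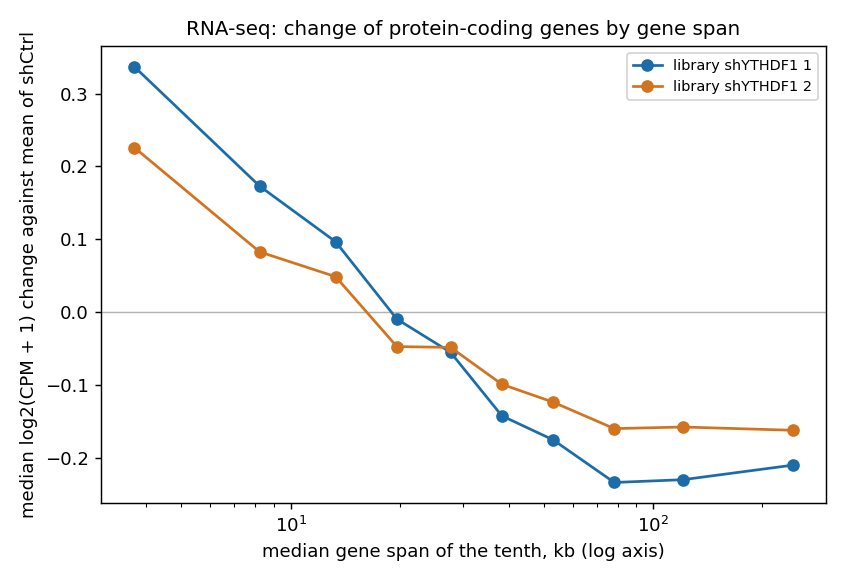
Protein-coding genes at 1 CPM or more were put in 10 groups of rising gene span; points give the median change in log2(CPM + 1) of 1 shYTHDF1 library against the mean of the 2 shCtrl libraries (vertical axis) by the median span of the group in kb (horizontal log axis). Both libraries start above 0 (0.34 and 0.23 in the shortest group) and end below it (-0.21 and -0.16 in the longest).

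The RIP comparison asked which transcripts came down with FLAG-YTHDF1. Matrix genes, Wnt pathway components, interferon-stimulated genes and genes with m6A peaks had higher ratios than random lists matched on input CPM, and transcripts of ribosomal proteins, histones and mitochondria lower ones. The random lists were not matched on gene span, along which the median log2 ratio rose from -0.70 (shortest 10% of coding genes) to 0.46 (longest 10%). The percentiles were not adjusted over the lists. Of 11262 genes measured, 2288 had an IP over input ratio of at least 2 and 2739 a ratio of at most the inverse. ARHGEF2 was enriched 2.32-fold (4466 IP and 365 input counts, 95% interval 2.09 to 2.60). YTHDF1 mRNA, which the plasmid also supplies, was at 1545 CPM in the IP and 1144 CPM in the input, 1.35-fold. There is no replicate and no control precipitation here, so the ratios compare 2 libraries. The count of enriched genes rose to 3542 with TMM scaling, which moves the median log2 ratio of all genes from 0.10 to 0.44. It was 1428 with totals that leave out mitochondrial and small RNA genes, where the log2 ratio of ARHGEF2 was 0.92, under the 2-fold bound.

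Among the highest ratios, the scaffold AKAP9 had 358 CPM in the IP and 40.4 CPM in the input, 8.81-fold (95% interval 7.79 to 10.1), followed by ANKRD12 (8.44-fold), the nuclear envelope protein SYNE2 (7.68-fold), the DNA repair kinase PRKDC (6.35-fold) and the protocadherin FAT1 (6.18-fold, 22564 CPM in the IP). ZNF615 (6.30-fold) and FRY (6.25-fold) rested on 9 and 7 input counts. F5 and LINC00950, a name that the reference pairs with a coding gene, had 2 input counts each, and their ratios of 9.45 and 7.48 have 95% intervals of 3.83 to 117 and 3.01 to 93.0. Among the lowest ratios, the ribosomal protein gene RPL39 was 49.0-fold lower in the IP, AAMDC 63.5-fold, the mitochondrial inner membrane gene ROMO1 36.5-fold and the ubiquitin-like gene UBL5 32.5-fold. RYR2, PID1, NPAS3, HFM1 and SLCO5A1 were 48.2-fold to 90.9-fold lower, and RIMS1, with 2 IP and 113 input counts, 199.8-fold (95% interval 80.4 to 2483). RIMS1, RYR2 and NPAS3 were under 0.1 CPM in the mean of the shCtrl RNA-seq libraries. PID1 (0.106 CPM), SLCO5A1 (0.124 CPM) and HFM1 (0.459 CPM) were also low there, while AAMDC, RPL39, ROMO1 and UBL5 were at 11.1 to 83.5 CPM.

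All 15 mitochondrially encoded genes (median 89.8-fold lower), all 15 measured replication-dependent histones (12.7-fold), all 14 nuclear-retained and small structured RNAs (18.2-fold) and 69 of 70 ribosomal protein genes (8.83-fold) were depleted. Mitochondrially encoded genes took 17.9% of the input gene counts and 0.121% of the IP counts; MT-RNR2 was at 66845 CPM in the input and 165 CPM in the IP. RPLP1 was 27.9-fold and RPS2 25.8-fold lower in the IP, HIST1H4C 31.5-fold and RMRP, the RNA of an RNase, 152-fold. These 4 directions held with TMM scaling, with a pseudocount of 5 and, for the 3 lists it can score, without mitochondrial and small RNA genes in the totals. The median of epithelial-mesenchymal and matrix genes was 1.85-fold higher in the IP (12 of 31 enriched, percentile 99.95 among 10000 input-matched random lists), with FN1 at 4.78-fold, ITGA2 at 3.64-fold and ITGA5 at 3.17-fold, and S100A4 17.3-fold lower. Wnt pathway components had a median 1.66-fold higher (9 of 27 enriched, percentile 99.3), with CTNNB1, which encodes beta-catenin, at 3.65-fold, the receptors FZD7 and FZD1 at 3.32-fold and 2.97-fold and APC at 3.14-fold. Interferon-stimulated genes had a median 1.72-fold higher (8 of 21 enriched, percentile 98.5), with IFIT1 at 4.29-fold and PARP14 at 4.04-fold, while ISG15 was 11.9-fold lower. Whether gene span accounts for these list medians was not tested, since no random lists matched on span were drawn for RIP.

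The remaining list medians lay within the middle 95% of their random lists. By percentile these were Wnt target genes at percentile 84.0 (NKD1 3.54-fold and JAG1 3.09-fold higher), immediate early genes 84.0 (KLF4 2.83-fold higher, AREG 4.52-fold lower), ATF4 and unfolded protein response 69.1 (SEL1L 2.21-fold higher), S phase 68.8, p53 targets 38.1 (RPS27L 8.78-fold and CDKN1A 3.53-fold lower), glycolysis and hypoxia 37.1 (GAPDH 7.25-fold lower), m6A machinery 34.9 (HNRNPA2B1 6.11-fold lower), cholesterol synthesis 16.5, intestinal genes 8.14 (KRT8 2.69-fold lower), G2 and mitosis 6.58 (CKS2 14.1-fold lower), translation factors 5.75 (EIF3H 7.95-fold lower) and ribosome biogenesis 5.18 (NPM1 9.95-fold lower, UTP20 5.41-fold higher). Some extreme members went the other way from those given. CD44 of the Wnt targets was 3.02-fold lower, and SDF2L1 and MANF of the ATF4 list were 3.98-fold and 2.37-fold lower. FCGBP (6 input counts) and CDX2 of the intestinal genes were 2.80-fold and 2.09-fold higher. Of the markers of other cell types only COL1A1 was measured, at 1.60-fold.

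Genes with an m6A peak in shCtrl were recovered better with YTHDF1. Their median ratio was 1.58-fold higher in the IP (4197 genes, 33.4% enriched), against 1.45-fold lower for the 6012 genes without a peak in any list (10.99% enriched). The medians differed by 1.19 log2 units (bootstrap 95% interval over genes, 1.13 to 1.24), and none of 10000 input-matched random lists reached the median of the genes with a peak (percentile 100). For genes with a peak in all 3 lists the difference was 1.30.

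**Figure D3:**
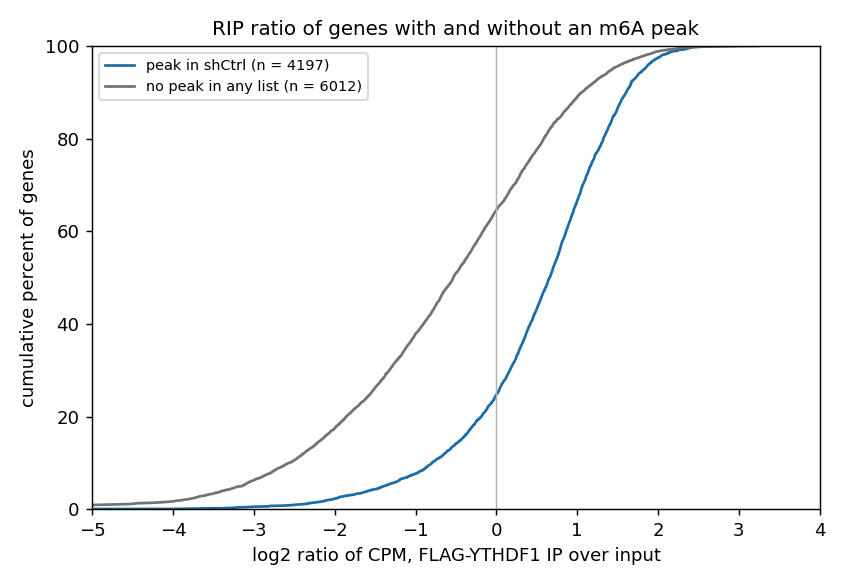
Cumulative percent of genes (vertical axis) by log2 ratio of CPM in the FLAG-YTHDF1 IP over input (horizontal axis), for 4197 genes with an m6A peak in shCtrl and 6012 genes without a peak in any list. The line for genes with a peak lies to the right, with a median of 0.66 against -0.53; 1 library per arm.

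The MeRIP comparison asked where m6A lay and whether the peaks differed with the hairpin. Peaks covered 4909 genes in shCtrl, 5139 in shYTHDF1-1 and 4630 in shYTHDF1-2, with a median exonic length of 282.5, 251 and 297 bp. Of the peaks placed on coding genes, 37.5%, 37.3% and 36.5% lay in the last 10% of the gene span, and 8.95%, 8.51% and 8.15% in the first 10%. The span includes introns, and how exonic sequence is spread along it was not measured. These shares therefore do not show that peaks favor the 3′ end beyond the position of exons. On ARHGEF2, shCtrl had 1 peak on the minus strand at 155947799 to 155950947 of chromosome 1 (550 exonic bp over 3 exon blocks, authors' p-value 0.00012), near the 3′ end of the gene. Both shYTHDF1 lists held a peak at this place, from 155947700 (550 bp) and from 155947749 (501 bp) to 155950848, and each a further short one, at 155951507 to 155952135 (151 bp) and 155951247 to 155951764 (101 bp). YTHDF1 had 2 peaks in shCtrl, at 63196660 to 63203542 and 63203641 to 63203788 of chromosome 20, 1 in shYTHDF1-1 (63202360 to 63203690) and 2 in shYTHDF1-2 (63202311 to 63203148 and 63203247 to 63203493).

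Most peaks were shared. Of the shCtrl peaks, 61.1% (Clopper-Pearson 95% interval 60.2 to 62.0) overlapped a peak in both shYTHDF1 lists and 17.2% a peak in neither. Of 8697 shYTHDF1-1 peaks that overlapped shYTHDF1-2, 11.9% (11.2 to 12.6) had no overlap in shCtrl. The same measure taken the other way around was no smaller: 16.9% of shCtrl peaks shared with shYTHDF1-1 were absent from shYTHDF1-2, and 13.2% of those shared with shYTHDF1-2 were absent from shYTHDF1-1. When at least 50% of both peaks had to overlap, the shares were 41.1% and 25.2%. With 1 list per sample and no signal per peak, a peak missing from a list is not a measured loss of methylation. The intervals treat peaks as independent, although 62.8% of the genes with a shCtrl peak had several. They do not measure spread between samples.

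Genes with the best ranked peaks in all 3 lists included NUFIP2, VCPIP1, FBXO30, CSTF2T, GJC1, FAM84B, TSC22D4, POLR1E and GJA3. Peaks of FAM171A2, MRPL18, SLC12A9, GAS2L1 and ERCC2 led among those only in shCtrl, which 493 genes had. Peaks of PLEKHA4, CHURC1-FNTB, ZNF81, ZNF572 and ZNF14 led among the 414 genes with peaks in both shYTHDF1 lists and not in shCtrl. Immediate early and AP-1 genes had a shCtrl peak in 24 of 31 expressed members (10.6 on average in expression-matched draws, percentile 100), p53 targets in 20 of 29 (11.1), Wnt pathway components in 19 of 29 (10.1), m6A machinery in 17 of 24 (9.43) and Wnt targets in 11 of 17 (5.99, percentile 99.2). Fewer than in the draws were found for ribosomal proteins (4 of 74 against 21.9), S phase genes (6 of 41 against 15.4) and G2 and mitosis genes (7 of 40 against 14.3). The draws were matched on expression only, not on exonic length or gene span. Whether length accounts for the higher and lower numbers was not tested. The other lists lay inside the middle 95% of the draws: ribosome biogenesis 19 of 41, epithelial-mesenchymal genes 16 of 32, ATF4 genes 15 of 31, translation factors 12 of 42, glycolysis 9 of 33, cholesterol synthesis 8 of 24, interferon genes 3 of 21 and intestinal genes 1 of 8. None of 4 expressed histones and not the 1 expressed marker of other cell types had one, the mitochondrially encoded genes were not scored, as their names did not match the reference, and the nuclear-retained list holds noncoding RNAs.

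The 3 assays were then joined, since the design looks for YTHDF1 targets. As a class, genes with a shCtrl m6A peak did not differ from all other tested genes in the RNA-seq by camera (adjusted p = 0.449). Their median log2 fold change was -0.03 (4412 genes) against 0.02 for 9478 genes without a peak in any list. That difference of -0.05 was 0.01 among protein-coding genes. Tested against no change, genes with a peak leaned lower without passing (fry adjusted p = 0.0695), while their median lay at percentile 95.2 of expression-matched lists. RIP-enriched genes had a median of -0.08 (2253 genes) against -0.05 for the other 8896 genes measured in RIP. That difference of -0.03 was not itself tested. Camera ranked RIP-enriched genes below all other tested genes, measured in RIP or not (camera adjusted p = 0.0423). With an estimated correlation this did not pass (camera adjusted p = 0.164). The difference turned to 0.01 without shYTHDF1 1. It was 0.00441 for genes with at least 500 RIP counts (camera adjusted p = 0.898 among these genes). The median of RIP-enriched genes lay at percentile 7.73 of expression-matched lists. Of 11149 genes measured in both assays, 1395 were RIP-enriched and had a shCtrl peak, where 844.9 would be if these were independent. Of the 1395, 57 were higher and 74 lower in shYTHDF1 RNA-seq, against 75.7 and 90.8 under independence. Gene span was not matched in these class comparisons, and both assays varied along it. In the shortest 10% of coding genes 12.9% were RIP-enriched, 16.6% called higher and 1.30% lower. In the longest 10% these shares were 30.5%, 1.12% and 8.98%. ARHGEF2 was RIP-enriched and had a peak, and its mRNA passed the test in neither direction.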

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

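The RNA-seq counts of 785 higher and 760 lower genes stayed within 1.5 times with other size factors, a filter of 1 CPM, DESeq2 and limma-voom, which called 1433, 1519, 1491 and 1472 of the same 1545 genes. They were 0 and 0 with no filter (5163 genes at an unadjusted p under 0.05), 269 and 183 with a 2-fold bound, and ranged from 0 to 3673 higher and from 3 to 3796 lower when 1 library was left out; the cause was not tested. The same replicate number does not pair the libraries (correlation of deviations 0.04); with the number as a replicate block the counts were 1261 and 1303 and all 1545 genes kept their call, while the p53 list lost its call (adjusted p = 0.0523) and no other list changed. Lists called were 6 to 9 over all settings except the estimated correlation, with 0. By fry 0 lists were called in 1 direction, and 16 when members may move either way. With 1 library left out the adjusted p of the p53 list ranged from 4.68e-08 to 0.663, the latter without shYTHDF1 2 and in the opposite direction. The difference of m6A-bearing genes, -0.05, was 0.00960 for protein-coding genes. RIP-enriched genes, at a difference of -0.03 from other genes measured in RIP, passed camera against all other tested genes. They no longer passed camera with a 1 CPM filter (difference -0.0302, adjusted p = 0.118), an estimated correlation (-0.0303, 0.164) or 4-fold enrichment (-0.0280, 0.277). The difference was 0.00441 for genes with at least 500 RIP counts, and ranged from -0.0660 to 0.00544 with 1 library left out. RIP-enriched genes numbered 3542 with TMM and 1428 without mitochondrial and small RNA genes in the totals, and depleted genes 1561 at a minimum of 500 counts, where fewer genes are measured. The RIP difference between genes with and without a peak was 1.17 to 1.21 with other count minimums, a pseudocount of 5, totals without mitochondrial and small RNA genes or coding genes only, and 1.30 with peaks in all 3 lists; TMM moves all ratios alike and cannot change it. Peak sharing was 41.1% and 25.2% with 50% overlap and 43.1% and 19.3% in the better ranked 50% of each list; leaving out 1 shYTHDF1 list, 70.4% to 73.6% of shCtrl peaks were overlapped, as a single list asks less. Of 102 genes named from RNA-seq, 23 did not pass with all libraries. The 79 that passed all lost their call with no filter, and nearly all of them did so without shCtrl 1 or 2. No sign of a called gene turned.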

Other observations

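The patterns in this part were found in these data and then tested on the same data. Each test was written down after its pattern was seen but before its own result, except the comparison of libraries within a group, which was chosen after the result was seen. A further pattern was tested first and then set aside for its small size, and the gene span pattern took its place after its trend had been seen. The pattern set aside was RIP-depleted coding genes with a mean under 0.1 CPM in the shCtrl RNA-seq libraries, 10 of 2544 genes (0.393%), with medians of 31.0 CPM in the RIP input and 2.54 CPM in the IP. The share was similar among RIP-enriched coding genes, 7 of 2140 (0.327%). Across these 10 genes the Spearman correlation of input counts with span was 0.2, and 20% had histone names.

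RIP recovery rose with gene span. The median log2 ratio was -0.70 in the 10% of measured coding genes with the shortest span and 0.46 in the 10% with the longest, although 45.6% and 34.9% of these genes had a shCtrl m6A peak.

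The fall of the RNA-seq change with gene span was set against 3 explanations. Expression level does not account for it, since the mean correlation within 10 groups of expression was -0.33. The correlation was also -0.34 among 3555 genes with no peak and a RIP ratio under 1, which argues against methylation as measured here. It does not exclude a part for binding, since RIP ratios under 1 still vary in size. Of the measured coding genes, 42.8% were RIP-depleted in the shortest 10% and 14.0% in the longest. Library preparation or RNA integrity stays open and may contribute, since libraries of a group also differed along span (correlation -0.17 for shYTHDF1 1 minus 2), though by less (0.12 and -0.05 log2 units in the shortest and longest 10%, and 0.04 and -0.01 for shCtrl). An effect of the hairpin on short genes in the cells was not tested.

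The called gene lists reported here were set against this trend with 10000 random lists matched on expression and span. The list medians lay at percentile 0 for S phase, G2 and mitosis, cholesterol synthesis, and glycolysis and hypoxia. They lay at 99.8 for ribosomal proteins and 99.9 for p53 targets. This argues against span as the whole account of the lists other than ribosomal proteins. For ribosomal proteins it cannot decide, since span was matched in broad groups only. Matched lists reached 0.24 of their 0.39 log2 units, and the 10% of coding genes with the shortest span had a median of 0.33. The random lists hold unrelated genes. The percentiles therefore do not allow for correlation within a list, estimated at 0.72 for ribosomal proteins and for p53 targets. The median of the library with the smaller change was 0.20 for ribosomal proteins, -0.32 for S phase, -0.35 for G2 and mitosis, -0.50 for cholesterol synthesis and -0.34 for glycolysis, each in the direction of the call. For p53 targets it was -0.13, against the call, so that call may rest on shYTHDF1 2. Lower cell cycle and sterol genes with the hairpin are a hypothesis only, with RNA integrity and culture conditions untested.

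The higher RIP ratio of m6A-bearing genes was set against 3 explanations. Within 100 groups of gene span and RNA-seq level the difference was 1.21 log2 units, positive in 99 of them, which argues against span and expression. Among genes at 1 CPM or more it was 1.20. That filter kept 4157 of 4197 genes with a peak and 5794 of 6012 without one. It could therefore hardly move the difference, and shows only that genes under 1 CPM were too few to account for it. With shCtrl RNA-seq in place of the RIP input, a comparison across kits, it was 1.35, which argues against the composition of the input library. Binding of YTHDF1 to m6A is a hypothesis consistent with these values, while unspecific binding to beads and the overexpression stay untested.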
